A study of Arabidopsis thaliana with 12 samples.

How the data were processed

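The series holds 12 single-channel array samples of total RNA, 6 of the prors1 mutant and 6 of the wild type, each with a replicate number from 1 to 6 in its title. The labels do not say whether these are separate plants, cultures or repeat measurements, so p-values measure the spread between these samples, which may be technical. One table of intensity values was deposited, with a column per sample. How the authors made these intensities (label, scanner, background correction and scaling) is not given in the sources used here. The deposited intensities are linear, never negative, and end just under 100, a value that 5 probes share on at least 1 array and 3 probes on all WT arrays, so these are bounds. Between 6.25% and 11.5% of probes per array were deposited at exactly 0.

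Probes were named from the platform annotation, which can be old, with locus names and symbols updated through gene identifiers to the TAIR10.1 gene table. It lists 1 gene for 692 probes, several for 870 and none for 1877, and 690 of the 692 matched the gene table. Probes with several genes or none stayed in the tests and were not named. No coordinates are given because the build behind the probes is not named.

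Settings were fixed before the data were examined. Array medians differed by up to 3.28-fold and array means by up to 1.16-fold, above the 1.1-fold set in advance, so arrays were quantile-scaled. Zeros and values under the 5th percentile of positive values (0.0467) were raised to that floor, which held 13.7% of values, and log2 was taken. Folds of genes near the floor are therefore understated. One row was averaged with another of the same locus, and 135 features at the floor in all samples were left out, which left 3303. Each feature was tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, genotype only, two-sided, Benjamini-Hochberg adjustment, threshold 0.05). The number of arrays limits the precision.

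The lists of 386 loci in 24 groups were written from general knowledge before the data were examined, and 20 loci were measured by single-gene features. Lists with at least 5 measured genes were tested with camera (preset correlation 0.01, then estimated) and fry, and 1 list qualified. A further 5 lists were drawn up after the annotation, and the intensities of a few of the brightest probes, had been seen but before any test. Genes were named by a rule: the 8 largest increases and 8 largest decreases among called single-gene features never at the floor, and up to 3 called members of each list with the largest change, or the member with the smallest p where none was called. All 20 measured genes of the fixed lists are given as well.

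Replicate numbers were checked for pairing. Over 815 bright features, deviations from the genotype means correlated at 0.498 to 0.659 between WT and prors1 samples of the same number, and at 0.346 to 0.489 over 2385 features never at the floor, so the numbers pair the samples across genotypes. What a number stands for is not stated. Within a genotype, samples 1-2, 3-4 and 5-6 had SDs of their log2 ratios of 0.16 to 0.276, against 0.295 to 0.67 for other pairs, with a consensus correlation of 0.551. If they are repeat measurements, p-values from 6 against 6 are too small, so counts with these pairs averaged, and with the pairs as a random block, are printed beside the main ones. These alternatives were added after seeing the data.

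The procedure was tested on simulated data with the 3303 features' means and spreads and 200 changed features, in 5 runs. Noise was drawn for each feature separately, so deviations shared over an array and the pairing of numbers across genotypes were not simulated. Equal numbers of features were raised and lowered, far fewer than the 1414 called in the real data. No zeros, floor or difference in array medians between the genotypes was put in. These runs therefore do not test how the scaling and the floor act on the real arrays. With independent samples it called 70% of 2-fold and 39.4% of 1.5-fold changes with 5.8 false calls on average. With a correlation of 0.55 within the pairs, 6 against 6 made 55.8 false calls, a random block for the pairs 4.2 and averaging 0.2. They called 73.6%, 52.2% and 7.4% of the 2-fold changes.

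Alternatives were the values as deposited, division by array medians, cyclic loess, floors at the 1st and 10th percentile, leaving out the dimmest 25% of features, testing each row as a probe, other variance models, a replicate block, an exact Wilcoxon test, a threshold of 0.01, and leaving out samples.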

Results

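Transcript levels were compared between an Arabidopsis thaliana line carrying the prors1 mutation and the wild type (WT), both in the Columbia 0 ecotype. PRORS1 is a prolyl-tRNA synthetase, an enzyme that charges transfer RNA with proline for protein synthesis, and the labels describe the mutant as lacking it. Total RNA of 6 WT and 6 prors1 samples was measured on single-channel arrays, and the deposited table held 3439 probes. The tissue, age and growth conditions of the plants were not given in the sources used here. After quantile scaling, 3303 features were tested, of which 658 stood for a single named gene. No probe named for PRORS1 itself was among the 692 single-gene probes, so the level of the mutated gene was not analysed here.

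The deposited signal was distributed differently in the 2 genotypes. The median intensity per array was 0.154 ± 0.0141 in WT and 0.349 ± 0.0852 in prors1 (SD, n = 6 each) on the authors' scale that ends at 100. All 6 prors1 values lay above all 6 WT values, a 2.27-fold difference of the means (exact two-sided permutation test, p = 0.00216, the smallest that 12 independent samples allow). An intensity of 0 was deposited for 382 ± 10.1 probes in WT and 246 ± 42.2 probes in prors1 (SD, n = 6 each, exact permutation p = 0.00216). The 34 brightest probes of each array held 46.2% ± 1.31 of the summed signal in WT and 33.8% ± 4.31 in prors1 (SD, n = 6 each, exact permutation p = 0.00216). The array means differed less, at 0.881 ± 0.0283 in WT and 0.966 ± 0.0252 in prors1 (SD, n = 6 each, exact permutation p = 0.00216). These 4 permutation tests took the 12 samples as independent and unpaired. Samples 1-2, 3-4 and 5-6 of each genotype resembled each other, so the p-values are too small if these are repeat measurements. The ratio of array medians was 2.29 for samples 1-2, 2.61 for 3-4 and 1.81 for 5-6. With only 3 independent sets per genotype, groups would not overlap by chance in 10% of cases.

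**Figure D1:**
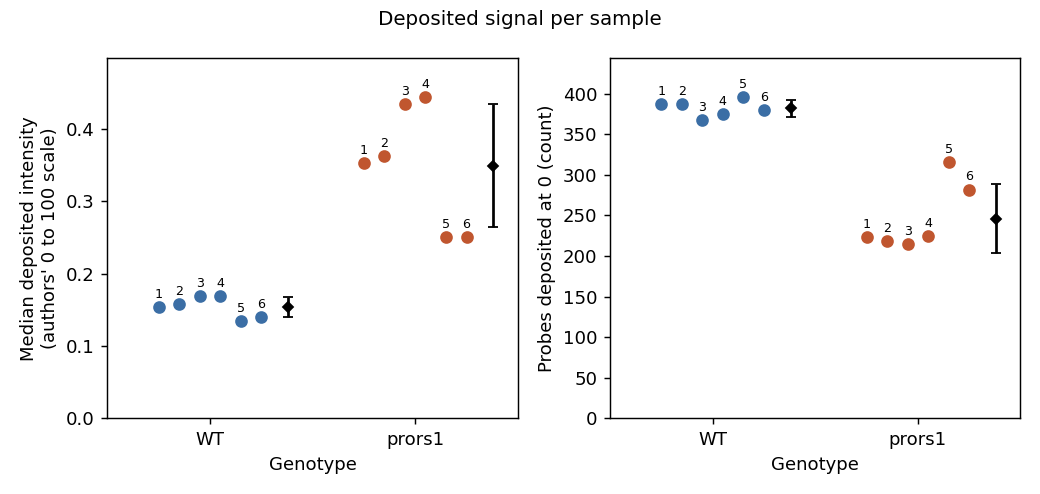
Median deposited intensity per sample on the authors' scale from 0 to 100 (left) and number of probes deposited at 0 (right), for WT and prors1. Points are samples with their replicate numbers, and black diamonds with bars are the mean and SD of 6 samples. The 6 prors1 samples have the higher medians and the fewer zeros.

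Because of this difference, changes are given after quantile scaling, relative to the distribution shared by all arrays. On the values as deposited, the median feature was 0.93 higher in prors1 on the log2 scale, against a shift of -0.02 after quantile scaling, -0.11 after division by each array's median and 0.04 after cyclic loess.

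Of the 7 measured nuclear genes of the photosynthetic lists, 5 were lower and none was higher in prors1 after quantile scaling, with 5 again when adjusted over the list alone and 4 lower with samples averaged as described below. Joined into one list they did not pass camera (adjusted p = 0.0615, and adjusted p = 0.21 with an estimated correlation). PSAN (AT5G64040), a subunit of photosystem I, fell by 0.88 ± 0.11 on the log2 scale (SE), from 3.05 ± 0.12 in WT to 2.17 ± 0.21 in prors1 (SD, n = 6 each), which is 1.84-fold lower at an adjusted p of 6.07e-05 in limma. PSBY (AT1G67740), a small photosystem II protein, was 2.11-fold lower (adjusted p = 7.6e-06), and PRK (AT1G32060), the phosphoribulokinase of the Calvin cycle, was 1.95-fold lower (adjusted p = 4.64e-05). LHB1B2 (AT2G34420), a chlorophyll a/b-binding protein of the photosystem II antenna, was 1.44-fold lower (adjusted p = 0.00324), with WT replicate 1 apart from the other WT samples and the call lost with samples averaged (adjusted p = 0.0778). SBPASE (AT3G55800), the Calvin cycle sedoheptulose-bisphosphatase, was 1.66-fold lower (adjusted p = 0.0281). That call was lost in 10 of 18 fits that left out a sample or a replicate number, and with the pairs of samples as a random block. PSBW (AT2G30570) and PSB27 (AT1G03600), both of photosystem II, did not pass the test, with log2 differences of 0.56 ± 0.29 and 0.27 ± 0.13 (SE), and both were called lower when arrays were divided by their medians (-0.83, adjusted p = 0.00177, and -0.69, adjusted p = 0.00342). With the replicate number as a block PSBW was called higher (adjusted p = 0.00324), as it was after cyclic loess (adjusted p = 0.037) and with arrayWeights (adjusted p = 0.0344), and PSB27 was called higher as deposited (adjusted p = 0.00625) and with arrayWeights (adjusted p = 0.0267). The decreases of PSAN, PSBY, PRK and LHB1B2 passed the test under all 4 scalings, but their size did not hold, since division by array medians gave -2.12, -2.26, -1.85 and -2.04 on the log2 scale. SBPASE was at 0.01 on the values as deposited, which is 0.90 below the median feature there.

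Both measured genes of chlorophyll synthesis were lower in prors1. CHLM (AT4G25080), the magnesium-protoporphyrin IX methyltransferase, was 1.52-fold lower (adjusted p = 0.00118), and AT1G74470, the geranylgeranyl reductase that makes the phytyl side chain, was 1.27-fold lower (adjusted p = 0.00913). All 6 prors1 values lay below all 6 WT values for both genes after quantile scaling, while the values as deposited overlapped between the genotypes for both. As deposited, CHLM stood at 0.21, which is 0.70 below the median feature, and AT1G74470 did not pass there (adjusted p = 0.0607) or after cyclic loess (adjusted p = 0.125). With samples averaged neither passed, at adjusted p = 0.0537 for CHLM and 0.155 for AT1G74470 in limma.

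Of 5 measured plastid ribosomal protein genes, 4 were lower and none was higher in limma after quantile scaling, again with 4 when adjusted over the list alone, and with 2 lower when samples were averaged. AT1G64510, the plastid ribosomal protein S6 gene, was 3.20-fold lower (adjusted p = 0.000344), although 4 of its 12 values lay at the intensity floor and prors1 replicate 5 lay apart, and on the values as deposited the difference was -0.38 and did not pass (adjusted p = 0.168). AT3G13120 (S10) was 1.82-fold lower (adjusted p = 0.0149), AT4G01310 (L5) was 1.48-fold lower (adjusted p = 0.0358, a call lost in 11 of the 18 fits and after cyclic loess at adjusted p = 0.0629) and AT3G54210 (L17) fell by 0.39 ± 0.10 on the log2 scale (SE, adjusted p = 0.00602). AT3G13120 and AT4G01310 also lost their calls with the pairs of samples as a random block. AT1G29070 (L34) had WT values at the floor and a difference of 0.60 ± 0.28 (SE, adjusted p = 0.109). As a set these 5 genes did not stand apart from all other features in the competitive camera test (p = 0.0895, and p = 0.114 with an estimated correlation). The one measured organellar aminoacyl-tRNA synthetase, the aspartyl enzyme AT4G33760, was 1.89-fold lower after quantile scaling (adjusted p = 0.000314). All its prors1 values lay below all WT values there, but the genotypes overlapped on the values as deposited. On the values as deposited AT3G13120, AT4G01310, AT3G54210 and AT4G33760 had positive differences of 0.07, 0.34, 0.30 and 0.12, all of them below the median feature. No ribosomal gene was called lower on those values, and AT3G54210 (adjusted p = 0.0453) and AT1G29070 (1.37, adjusted p = 0.0141) were called higher.

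The other fixed lists had few measured members. AT3G52960, the plastid type II peroxiredoxin E, was 1.52-fold higher (adjusted p = 0.00275) and was the 1 gene of all fixed lists that was higher in prors1. When arrays were divided by their medians its difference was 0.05 and did not pass (adjusted p = 0.775). With samples averaged the call was lost (adjusted p = 0.0736). AT1G24360, the ketoacyl-acyl carrier protein reductase of fatty acid synthesis, was 1.54-fold lower (adjusted p = 0.0245), with a difference of 0.65 on the values as deposited. Its call was lost with arrays divided by their medians (adjusted p = 0.0879), with the pairs of samples as a random block and in 5 of the 18 fits that left out samples. The acyl carrier protein thioesterase FATB (AT1G08510) had a difference of 0.26 ± 0.40 (SE, adjusted p = 0.634). In branched-chain amino acid synthesis, the dihydroxyacid dehydratase AT3G23940 had a difference of 0.18 ± 0.10 (adjusted p = 0.175) and the ketol-acid reductoisomerase AT3G58610 one of -0.22 ± 0.13 (SE, adjusted p = 0.214). Without scaling FATB (1.39, adjusted p = 0.00509), AT3G23940 (0.67, adjusted p = 0.000162) and AT3G58610 (0.93, adjusted p = 0.000512) were called higher, and AT3G23940 was called lower with arrays divided by their medians (-0.47, adjusted p = 0.0452). Of the 24 lists, 14 had no member among the single-gene probes, so among others proline metabolism, chaperones, protein import, isoprenoids, starch, photorespiration and the markers of roots, seeds and senescence were not analysed here.

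**Figure D2:**
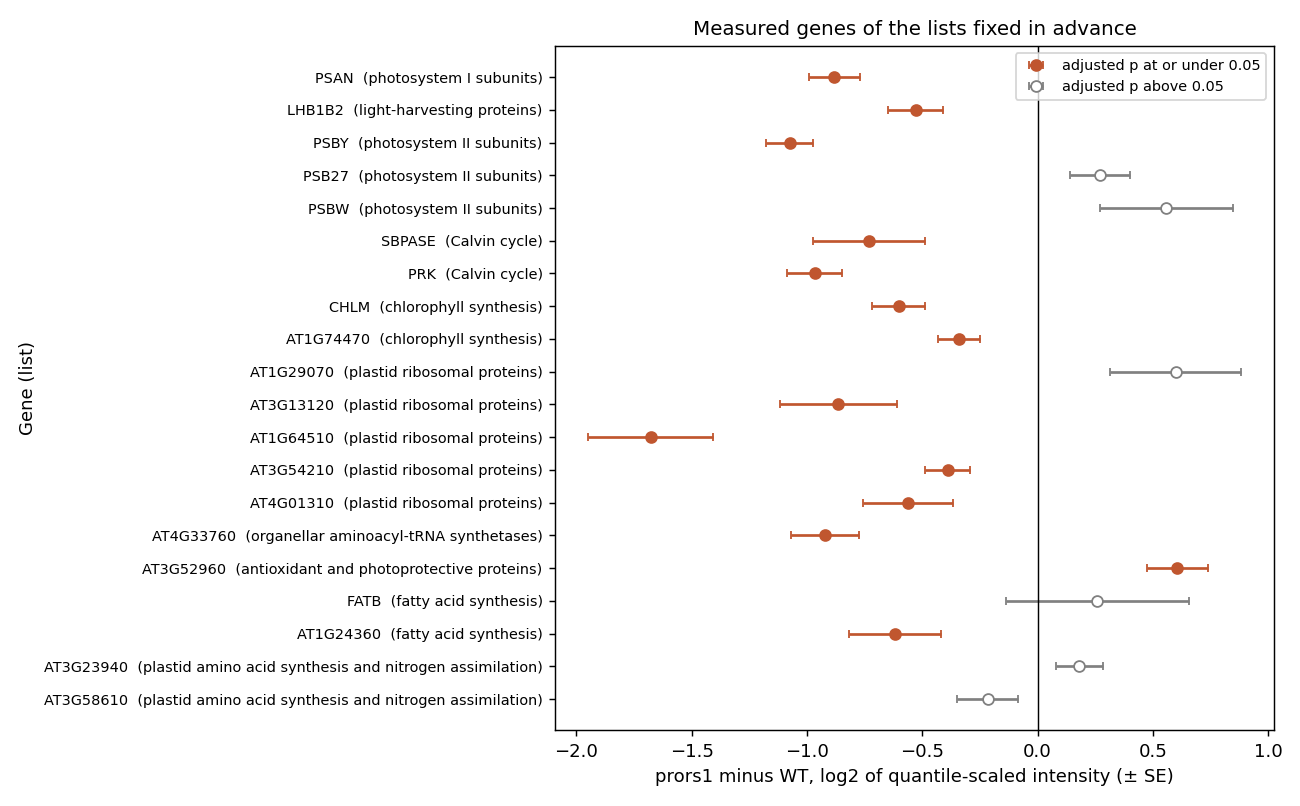
Difference between prors1 and WT for the 20 measured genes of the lists fixed in advance, as log2 of quantile-scaled intensity on the horizontal axis, with each gene and its list on the vertical axis. Points are limma estimates with SE bars (6 samples per genotype), filled where the adjusted p is at or under 0.05. Of the 20 genes, 13 lie below 0 with a filled point and 1 lies above 0 with a filled point, and relative to the median feature none of these 14 changed sign over the 4 scalings.

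Over all lists, 13 of the 20 measured genes (65%) were lower in prors1, against 120 of the 638 other single-gene features (18.8%; Fisher's exact test, two-sided, p = 1.19e-05). With the values as deposited the shares that were lower were 4 of 20 (20%) and 14 of 633 (2.21%), p = 0.00149 in the same exact test. More of the 20 genes, 7, were called higher there, where 430 of all 653 single-gene features were higher. With samples averaged the shares that were lower were 7 of 20 (35%) and 51 of 638 (7.99%), p = 0.000902 in Fisher's exact test. Fisher's test takes genes as independent, which genes measured on the same samples need not be. Its p-values do not measure the spread between samples. When the lists were joined, camera gave p = 0.00629, and p = 0.0138 with an estimated correlation. The joining of the lists was chosen after the probe annotation had been seen, and the comparison of shares was not among the tests fixed in advance.

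Across the whole array, 1414 of 3303 features differed between the genotypes at an adjusted p of 0.05 in limma. Of these, 649 were higher and 765 lower in prors1, and 248 and 267 of them changed at least 2-fold. The samples numbered 1-2, 3-4 and 5-6 of each genotype resembled each other, and with these averaged, so that n = 3 per genotype, 749 features were called, 358 higher and 391 lower, 741 of them among the 1414. With these sets as a random block 996 features were called, 454 higher and 542 lower, all among the 1414. On the values as deposited the split was 2030 higher and 182 lower, that is 91.8% higher against 45.9% after quantile scaling, and it was 552 and 1003 (35.5% higher) when arrays were divided by their medians. Of 3266 features tested under all 4 scalings, 414 were higher and 172 lower under each, while 297 were called in opposite directions by different scalings, among them 110 that were lower after quantile scaling and higher as deposited. After quantile scaling the 2 genotypes did not overlap for 841 features (25.5%), where chance would give 0.22% of 12 independent samples. With the averaged sets as units it was 1392 features (42.1%), where chance would give 10%.

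Among single-gene features, 136 were higher and 133 lower after quantile scaling. The split was 430 and 18 as deposited, 121 and 167 with arrays divided by their medians, 149 and 118 after cyclic loess, and 77 and 58 with samples averaged. Under all 4 scalings 88 were higher and 16 lower, and 56 were called in opposite directions. The largest increase after quantile scaling, among features never at the floor, was that of AT4G35660, which rose 4.72-fold from 1.60 ± 0.26 to 3.84 ± 0.21 on the log2 scale (SD, n = 6 each, adjusted p = 3.29e-07 in limma). Its difference was 0.96 with arrays divided by their medians, below the 1.70 of PRA1.B6 there, and 2.11 against 2.85 as deposited, so this order belongs to the scaling. AT4G18180 followed with 3.72-fold (adjusted p = 2.81e-06), then AT5G39980, a pentatricopeptide repeat protein gene, with 3.35-fold (adjusted p = 2.06e-07), and PRA1.B6 (AT5G07110), of the prenylated Rab acceptor family, with 3.33-fold (adjusted p = 3.51e-05). AT5G40050, AT4G22370, AT1G73470 and AT1G73740 were 2.96-, 2.94-, 2.92- and 2.86-fold higher, with WT replicate 5 apart from the other WT samples for AT4G22370. All 8 had prors1 values above every WT value, and all 8 were called higher under the 4 scalings and with samples averaged.

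The largest decrease after quantile scaling among single-gene features measured above the floor on every array was that of AT1G21500, which was 3.13-fold lower (0.14 ± 0.14 in WT and -1.51 ± 0.33 in prors1 on the log2 scale, SD, n = 6 each, adjusted p = 4.52e-06). PSBY fell further than AT1G21500 as deposited (-1.12 against -0.98) and with arrays divided by their medians (-2.26 against -2.13). AT1G62780, AT2G29180, AT4G05070 and AT4G01810 were 2.94-, 2.91-, 2.88- and 2.74-fold lower. AGL54 (AT5G27090), a MADS-box transcription factor gene, was 2.65-fold lower (adjusted p = 0.000204), AT5G59060 was 2.62-fold lower (adjusted p = 0.00247), and CBL (AT3G57050), the cystathionine beta-lyase of methionine synthesis, fell by 1.32 ± 0.12 on the log2 scale (SE, adjusted p = 3.9e-06). After quantile scaling all 8 had prors1 values below every WT value. On the values as deposited AT4G01810, AGL54 and CBL kept the direction but not the call, and with samples averaged AT5G59060 missed the threshold (adjusted p = 0.0535).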

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

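In 5 of 96 groups of 6 samples checked for a sample far from the others, 1 sample stood apart, where chance gives about 1 in 20. The tests of the array distribution were chosen after the result was seen, except that of an added constant, and so was the test of resemblance between samples.

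In WT, LHB1B2 was lowest in replicate 1 at 4.64 on the log2 scale, with the next value at 4.83. PIFI (AT3G15840) was lowest in WT replicate 1 at -3.41, with the next at -2.59, and highest in prors1 replicate 6 at -2.67, with the next at -3.86. The plastid ribosomal gene AT1G64510 was highest in prors1 replicate 5 at -2.79, with the next at -3.94. AT4G22370 was lowest in WT replicate 5 at -4.07, with the next at -2.67.

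The higher array medians and fewer zeros of prors1 appeared in each set of samples, at 2.29-fold for 1-2, 2.61-fold for 3-4 and 1.81-fold for 5-6. Loss of the brightest signals under a fixed total would raise all other probes by one factor, but the signal summed outside the 34 brightest rose 1.35-fold against 2.27-fold for the median, and one multiplying factor is argued against by a log2 ratio that was 1.002 larger in the dimmest 25% of probes than in the brightest. A single added constant is argued against as well. The 162 probes at 0 in all WT samples had a median prors1 value that was 0.015 of the rise of the array median. The median linear difference was 0.108 in the dimmest 25% and 0.189 in the 25% above it. It was 0.246 in the 25% next to the brightest and 0.223 in the brightest 25% (95% interval 0.172 to 0.29), with no further rise of the median there. That interval came from resampling probes, so it measures the spread between probes and not between samples. These shares of 25% were of the 2705 probes above 0 and below the top of the scale on every array. Zeros may hide values below background, which weakens the value of 0.015 but not the linear differences. A change in the RNA of the plants and a non-linear response of the arrays both stay open, because every set (smallest ratio 1.81) compares the genotypes on different measurements with no control signal.

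Within a genotype the largest SD of log2 ratios between samples 1-2, 3-4 or 5-6 was 0.276, below the smallest between other samples, 0.295. Repeat measurements of one RNA or one hybridisation could give this, as could plants grown together, and the labels do not separate these. Between genotypes, deviations over 815 bright features correlated at 0.498 to 0.659 for the same number and 0.274 to 0.43 for the partner number. For other numbers it was -0.433 to 0.0133. The sets are thus shared between genotypes, with a closer resemblance for the same number, and what this reflects was not tested.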

How the results depend on the processing

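The averaging of samples, their random block and the omission of a whole set were chosen after seeing the data. On the values as deposited, 2212 features were called, 2030 higher and 182 lower, and of the fixed-list genes 4 were lower and 7 higher. There the differences of AT1G24360 (0.65), AT3G13120 (0.067), AT3G15840 (0.12), AT3G54210 (0.30), SBPASE AT3G55800 (0.014), AT3G58610 (0.93), AT4G01310 (0.34), CHLM AT4G25080 (0.21) and AT4G33760 (0.12) changed sign. Because that scaling lifts the median feature by 0.93, these genes, apart from AT3G58610, still lay below the median. Dividing arrays by their medians turned PSB27 AT1G03600 (-0.69), XERICO AT2G04240 (-0.29), PSBW AT2G30570 (-0.83), AT3G04210 (-0.25) and AT3G23940 (-0.47), and FATB AT1G08510 turned with the floor at the 10th percentile (-0.082) and without samples 1 and 2 (-0.027). The count of fixed-list genes that were higher, 1 in the main test, was 0 with arrays divided by their medians, 2 with cyclic loess, 2 with the floor at the 1st percentile, 3 with arrayWeights, 2 with the replicate block, 0 with samples averaged (with or without the set as a block), 0 without samples 1 and 2, 0 without samples 3 and 4 and 4 without samples 5 and 6.

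Averaging samples 1-2, 3-4 and 5-6 called 749 features, 358 higher and 391 lower, with 7 fixed-list genes lower, and 28 of the 38 named genes called in the main test. The 10 lost were LHB1B2, CHLM, AT1G74470, AT3G54210, AT4G01310, AT1G24360, AT3G52960, AT3G04210, ATAB2 and AT5G59060. Without samples 1 and 2 there were 909 calls, 429 higher and 480 lower, and 8 fixed-list genes lower. Without samples 3 and 4 there were 1081 calls and without samples 5 and 6 there were 1564, so the number of samples alone does not set the count. Leaving out 1 sample or 1 replicate number gave 1181 to 1490 calls, 541 to 690 higher and 639 to 800 lower, with 10 to 13 fixed-list genes lower and 1 to 2 higher. The fixed plastid ribosomal list had camera p-values of 0.0691 to 0.127 over those settings, and fry, which asks another question, gave 8.93e-05. SBPASE lost its call in 10 of the 18 omissions, AT4G01310 in 11, AT1G24360 in 5, AT3G04210 in 2 and AT3G13120 in 1. The replicate block, which uses the pairing of the numbers, called 1664 features, 789 higher and 875 lower and ended no call of a named gene, and it added PSBW as higher. With the sets averaged and as a block 1077 features were called, 525 higher and 552 lower, and PSBW was not. The random block called 996, with 9 fixed-list genes lower, and kept 33 of the 38 named calls, losing SBPASE, AT3G13120, AT4G01310, AT1G24360 and PIFI. Over all 1579 values of named genes under alternatives, 1465 kept direction and side of the threshold. A further 84 kept direction but lost the call, 14 kept direction and gained it, and 16 changed sign. Calls lost or gained with a change of sign are counted only among those 16. No list test was run with the dimmest 25% of features left out (fewer than 5 members remained), with the Wilcoxon test, at the threshold of 0.01 or with the random block, and the alternatives for PRORS1 were not run because no single-gene probe was named for it. The cause of these changes was not tested, apart from the shift of the median feature as deposited. Signal over background limits the dim genes, since 13.7% of values lay at the floor.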

Other observations

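Of 24 measured genes for pentatricopeptide repeat (PPR) and mTERF proteins, which act on RNA and transcription in plastids and mitochondria, 9 were higher, 2 lower and 13 did not pass the test, with 10 and 2 when adjusted over the list alone. AT5G39980 was 3.35-fold, AT3G49740 2.65-fold and AT1G31790 2.60-fold higher in prors1. The list as a whole did not pass camera after adjustment over the 5 lists drawn up after the annotation was seen (adjusted p = 0.0615, and adjusted p = 0.262 with an estimated correlation). The share of higher genes, 37.5% against 20% of other single-gene features, gave p = 0.0668 in Fisher's exact test, with p = 0.388 on the values as deposited, 0.421 with arrays divided by their medians, 0.0878 after cyclic loess and 0.0152 with samples averaged. That test takes genes as independent here too. AT5G39980, AT3G49740 and AT1G31790 were called higher under all 4 scalings. The joined photosynthetic genes had the same adjusted p of 0.0615 (0.21 with an estimated correlation).

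Of 11 measured genes for thylakoid complex biogenesis and the NDH complex, 3 were higher and 4 lower, with 3 and 4 adjusted over the list alone (camera adjusted p = 0.703, and 0.799 with an estimated correlation). AT1G22700 was 1.94-fold higher, while PIFI (AT3G15840) and ATAB2 (AT3G08010) were 2.48- and 2.52-fold lower, with overlapping groups, 1 and 3 values at the floor, and no call on the values as deposited (0.12, adjusted p = 0.743, and -0.14, adjusted p = 0.671). PIFI also lost its call with the pairs of samples as a random block, and ATAB2 with samples averaged. Of 5 plastid redox genes, AT3G52960 was higher and AT2G04700, the ferredoxin-thioredoxin reductase catalytic subunit, was 2.23-fold lower, a call lost on the values as deposited (adjusted p = 0.122; camera adjusted p = 0.49). Of 5 measured stress-responsive genes, XERICO (AT2G04240) was 1.65-fold and AT3G04210 1.39-fold higher and none was lower, with 3 higher when adjusted over the list alone (camera adjusted p = 0.223). Both XERICO and AT3G04210 turned when arrays were divided by their medians, and AT3G04210 lost its call with samples averaged.

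The tests of scaling below, the margin around the percentile bounds and the splits of averaged sets were chosen after the result was seen. The lower photosynthesis genes and the higher PPR and mTERF genes were each set against the scaling and against brightness as explanations. Relative to the median feature, the photosynthetic median was at most -0.707 and the PPR and mTERF median at least 0.149 over the 4 scalings, so neither changed sign. Against random lists matched on brightness under each scaling, the photosynthetic median lay at percentiles 1.35 to 2.43 and that of PPR and mTERF genes at 96.4 to 99.1, so scaling stays open for the PPR and mTERF list, inside the 95% range under some scalings, and for the photosynthetic list as a whole, too near its bound after quantile scaling. Of the 5 photosynthetic genes called lower, PSAN, PSBY, PRK and LHB1B2 were called lower under all 4 scalings. This argues against scaling for the direction of each of these genes. They were grouped by that result, so it does not speak for the list as a whole. The highest log2 difference of these genes was -0.469, but their size changed with the scaling. LHB1B2 lost its call with samples averaged. The 4 scalings are related, since division by array medians only shifts each array's deposited log2 values above the floor. For SBPASE scaling stays open, at 0.0138 as deposited. Among 10000 random lists matched on brightness, the PPR and mTERF median of 0.35 lay at percentile 99. This argues against a brightness-dependent bias common to all features as the cause after quantile scaling. The photosynthetic median of -0.73 over 7 genes lay at percentile 2.47, too near the bound of 2.5 to exclude such a bias. The random lists were drawn from all features, not from single-gene features alone. Of the called features, 50.6% were higher among single-gene features and 44.8% among other probes. Whether this moved the percentiles was not tested. A hypothesis that transcripts for organelle RNA processing and for photosynthesis respond in opposite directions in prors1 may be worth a test on independent samples.

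Other splits of the samples were refitted. Of 100 splits of the 12 samples, 1, the real one, called as many as 1414 features, and the highest other split called 395, with 5 of the 6 samples of each genotype still together. Of the 32 splits that part all 6 numbered pairs, again 1, the real one, called as many, and the highest other called 1. These splits would exclude chance for the total count only if the 12 samples were independent. Samples 1-2, 3-4 and 5-6 resemble each other (largest SD 0.276), and a split that parts resembling samples widens the spread within each side. Chance is therefore not excluded by these splits. Simulated data with no change and a correlation of 0.55 within those sets gave 3.4 calls on average for 6 against 6, and 0 with sets averaged or as a random block, where the real data gave 1414, 749 and 996. The simulated noise was separate for each feature, with no deviation shared over an array and no pairing of numbers across genotypes. These simulated counts therefore cannot decide about chance. With the averaged sets as units the real split called 749 features and the highest other 0, and these 10 splits are too few for a share under 0.05.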
